A study of Mus musculus with 3 samples.

How the data were processed

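H3K9me3 ChIP-seq was made from lungs of newborn male CD-1 mice, with 10 mice pooled per group before the immunoprecipitation and 1 library for each of the control and DMA groups. A pooled input library belongs to the series and was not analysed here. Libraries were sequenced on an Illumina instrument, per the labels' protocols. BWA 0.7.12 and MACS are named in the submitters' processing notes without their roles, and the build is mm10 (GRCm38).

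The authors deposited 1 list of islands per library, with the chromosome, the first and last base of the island and a whole-number count of reads. The file names, which the authors gave, state windows of 200 bp, gaps of 600 bp, a false discovery rate of 1E-10, a tag for normalisation and a filter. How the normalisation and the filter were done is not given in the sources used here, so reads may have been thinned before counting. The counts sum to different totals, 5575840 in the control and 4029403 in the DMA library, and were used as deposited. They are reads in islands and not the depth of the libraries. Start positions count from 0 in the lists and from 1 here.

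Islands of the libraries were compared by overlap of at least 1 bp with bedtools 2.31.1 and Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Shares carry exact binomial 95% intervals, and 100 random placements on the same chromosome gave the chance overlap. Overlapping islands of both libraries were merged into regions, and the DMA and control reads of a region were compared as a log2 ratio with an exact conditional binomial interval. Reads outside called islands are not in the lists, so a region called over a shorter stretch in 1 library has fewer reads for that reason as well. Intervals of shares and of single ratios cover counting error only, and PCR copies are not independent molecules. Intervals of a median log2 ratio come from the order of the regions and reflect the spread between regions. In the closing section, the log2 interval of matched X regions and that of the unmatched X share came from resampling regions. The interval for islands in genes came from resampling the autosomes. No interval covers the spread between mice.

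Genes came from a table of the GRCm38.p6 annotation, the same build, with start and end but no strand, exons or transcript starts. The plan had a window of 2 kb upstream of each gene. Without strand, 2 kb on both sides were used, and context was limited to gene bodies against the rest. A gene was marked where at least 1 bp of an island fell in that window. Each of 14 gene lists was compared with 10000 random lists of protein-coding genes matched on gene length in 20 bins. The percentiles of the net count (DMA-only minus control-only members), of the median and of the mean difference in covered share describe these libraries and are not tests. The median difference was 0 for 11 of the lists, and the mean was added after that was seen. Since lists with more cover can lose more of it, members covered in the control library were also compared, after the data were seen, with 10000 random lists of protein-coding genes matched on covered bases and reads per kb in that library (cover-matched lists). The measure was the total of bases covered in the DMA library as a percentage of the total covered in the control library, which counts bases gained as well as lost and can pass 100%. All listed symbols matched an annotated gene. The list of imprinted genes includes non-coding ones. The zinc finger list goes by symbol and holds some genes without a KRAB domain.

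Named genes were set by a rule written before the data were examined. It took the 8 protein-coding genes under the longest islands found in each library only, passing over predicted genes, the 5 highest and 5 lowest ratios among shared regions with at least 100 reads, up to 4 members per list and direction with the largest difference in covered bases, and Krt8, Cdkn1a, Ccnd1, As3mt, Suv39h1 and Setdb1. The strongest shared domains and the strongest islands found in 1 library only were named after their values were seen.

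The procedures were tested on simulated data. For 23785 shared regions with 200 changed by 4-fold, the interval held the true ratio in 95.8% of regions and 100% of the changed regions ranked at the top or bottom. These counts were drawn with counting error only, which is what the interval assumes, so this checks the computation. Further spread and differences in called length were not simulated, so it does not show how well real ratios are ranked. Of 100 random lists of 50 genes, 1% fell outside the central 95% of percentiles, and a list with 10 planted losses lay at percentile 0. This checks the computation for the net count only, with genes drawn singly. The mean, median and cover-matched measures and clustered gene families were not simulated. Alternatives were stricter islands (upper 50% by reads, at least 2 kb), other definitions of overlap, equal numbers of islands, autosomes only, other gene windows, and other scales of the counts.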

Results

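H3K9me3, the histone mark of constitutive heterochromatin and of silenced repeats and gene clusters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the lungs of newborn male CD-1 mice, an outbred stock. The question was how exposure in the womb to dimethylarsinic acid (DMA), a methylated metabolite of inorganic arsenic, altered the mark. Parents were mated at 10 weeks of age. Dams then drank water with 0 ppm (control) or 200 ppm DMA over 10 days from day 8 after mating, and the lungs of the offspring were taken on postnatal day 0. Material of 10 males was pooled in each group before the immunoprecipitation, so each group had 1 library. The spread between mice was not measurable and no test between the conditions was possible. The intervals below cover counting error, or the spread between regions or chromosomes, and not the spread between mice. The deposited lists give the islands, which are stretches enriched in H3K9me3, with a whole-number read count for each. The control islands held 5575840 reads and the DMA islands 4029403 reads. The total sequencing depth of each library is not given in the sources used here.

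The islands of the DMA library were shorter and held fewer reads, and as deposited there were more of them. It listed 37104 islands against 35363 in the control library, 4.92% more. The order turned with islands of at least 2 kb, of which the DMA library had 30064 and the control library 31467. The DMA islands covered 147 Mb against 179 Mb, a difference of -18.0%, and the reads in islands differed by -27.7%. The median island was 3200 bp long with 72 reads in the DMA library and 4000 bp long with 103 reads in the control library. The mean read density over all islands was 27.4 reads per kb in the DMA library and 31.1 in the control library. Across the 19 autosomes the covered length in the DMA library lay between 0.722 (chromosome 11) and 0.889 (chromosome 1) of that in the control library.

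The strongest domains were held by both libraries. The largest read count in each was over the plectin gene Plec on chromosome 15 (mm10, 76166201 to 76203400), with 15535 control and 9626 DMA reads. It was followed by the protocadherin gamma cluster on chromosome 18 (37666801 to 37778200), whose genes encode neuronal adhesion proteins chosen by promoter, with 12162 control and 9548 DMA reads. Zfhx3 on chromosome 8 held 5826 and 3818 reads, and the titin gene Ttn on chromosome 2 held 5002 and 4311. Of the control islands 27818 (78.7%, exact 95% interval 78.2 to 79.1%) overlapped a DMA island, and of the DMA islands 28577 (77.0%, 76.6 to 77.4%) overlapped a control island. Random placement of the islands on their own chromosomes gave medians of 12.7% and 12.4%. Islands shared 114 Mb, a Jaccard index of 0.536, and 77.4% of DMA bases but 63.5% of control bases lay in islands of the other library.

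Islands without a counterpart numbered 7545 in the control library and 8527 in the DMA library, and their read counts were low. The order of the counts turned with islands of at least 2 kb (8022 control and 6086 DMA), with equal numbers of islands (8006 and 7330) and with at least 50% of the island covered (10497 and 9459). Their median read count was 68 in the control library and 40 in the DMA library, against 117 and 88 in the shared islands. Of the islands with at least 400 reads, 18 of 2145 control islands and 5 of 926 DMA islands had no counterpart. An island missing from a list lay below the threshold of the caller or was left out by the filter named in the list, and is not shown to lack the mark.

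**Figure D1:**
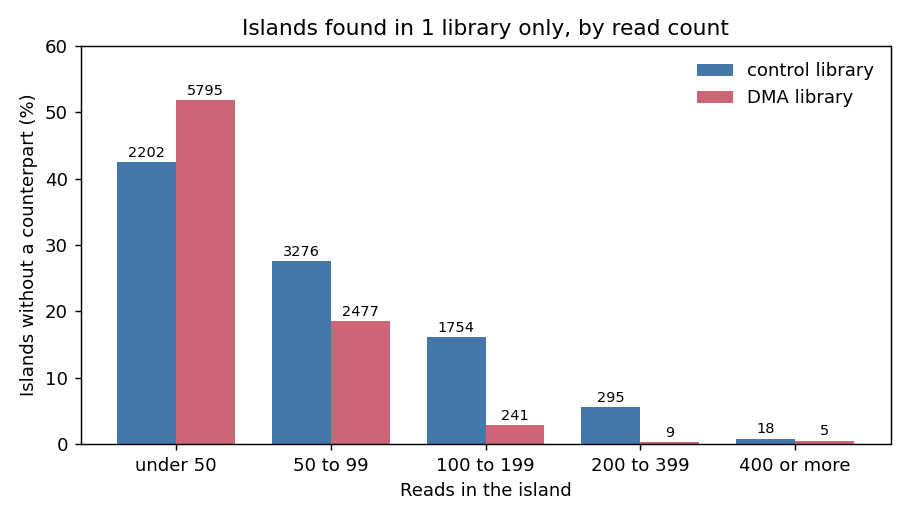
Share of the islands of each library (vertical axis, percent) that did not overlap an island of the other library, by the number of reads in the island (horizontal axis), with the number of such islands above each bar. The share fell from 42.5% of control and 51.9% of DMA islands with under 50 reads to 0.839% and 0.540% of those with 400 reads or more.

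Under named protein-coding genes, the longest islands found in the control library only were 31.6 kb over the kinase gene Mast3 on chromosome 8 (70763001 to 70794600, 744 reads), 28.6 kb over Psd on chromosome 19 (582 reads) and 26.6 kb over the polarity gene Llgl2 on chromosome 11 (656 reads). The fourth, of 22.6 kb, lay over the zinc finger gene Zfp110. A 21.4 kb island lay in Smad3, a transducer of TGF-beta signals, on chromosome 9 (525 reads). Smad3 kept other islands in both libraries, with 43.4 kb covered in the control and 8.2 kb in the DMA library. Rilpl1, Txnip, which encodes the thioredoxin-interacting protein, and Ushbp1 lay under control islands of 19.8, 19.6 and 19.4 kb. Within the gene and 2 kb of it lay 19.8, 6.06 and 14.5 kb of these islands. Under named protein-coding genes, the longest islands found in the DMA library only were shorter, with 20.6 kb in the dynein gene Dnah8 on chromosome 17 (30640601 to 30661200, 774 reads), 11.6 kb over the zinc finger gene Zfp329, and 8.0 to 9.8 kb at Ctnnd2, Trappc9, Dcdc2a, Pramel26, Caln1 and Sash1. Only 0.728 kb of the Dcdc2a island lay in the gene body. Of these 8 genes only Zfp329 and Dcdc2a had no island in the control library. Dnah8 (122 kb in the control and 101 kb in the DMA library), Trappc9 (59.4 and 48.6 kb) and Caln1 (189 and 169 kb) were covered less in the DMA library in all, within the gene and 2 kb of it.

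The strongest island found in 1 library only was at Zfp110 (NCBI gene 65020), a zinc finger gene on chromosome 7. In the control library it ran from 12833601 to 12856200, 22.6 kb, with 2481 reads or 110 reads per kb. The nearest DMA island began 8.0 kb away. The neighbouring gene Zfp329 (NCBI gene 67230) was covered in the DMA library only, from 12807401 to 12819000, with 589 reads. The islands on both sides of the pair were shared, with 218 control and 191 DMA reads on one side and 242 and 211 on the other.

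**Figure D2:**
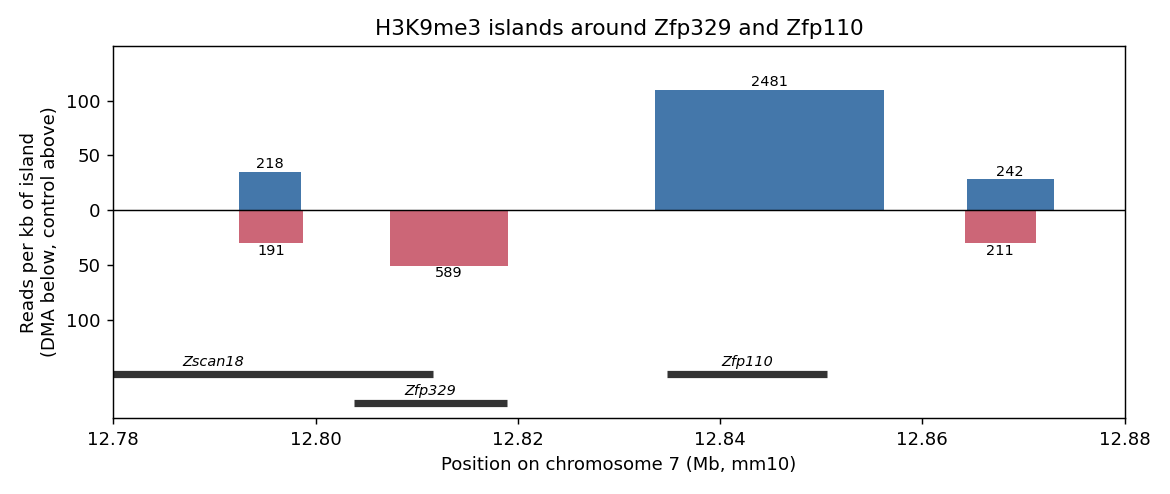
H3K9me3 islands along chromosome 7 (horizontal axis, Mb, mm10) as boxes whose height is the read density in reads per kb, control above and DMA below the line, with the read count of each island and the protein-coding genes as bars. The 2481-read control island over Zfp110 and the 589-read DMA island over Zfp329 have no counterpart, while both flanking islands do.

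Reads in the 27036 merged regions held by both libraries were fewer in the DMA library. The median log2 ratio of DMA to control was -0.38 (95% interval of the median -0.39 to -0.38), and 81.9% of the regions lay below 0. Part of this came with called length, as the median region had 3800 bp of DMA island against 4400 bp of control island. Over the 11340 regions that both libraries covered by at least 80%, a set chosen after the data were seen, the median was -0.28. The shift was global and its sign rests on the scale: after scaling to the total reads in islands the median was 0.087. Single regions are therefore also given relative to the median of -0.38.

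Among regions with at least 100 reads, the lowest ratio was at Celf5. Over this gene, an RNA-binding protein gene on chromosome 10 (81450801 to 81477200), 566 control reads stood against 40 DMA reads, a log2 ratio of -3.82 (-4.32 to -3.36) and of -3.44 relative to the median. The transcription factor genes Dmrt3 (201 to 20 reads, -3.33) and Tlx1 (365 to 38 reads, -3.26), both on chromosome 19, and regions in Rbfox3 (-3.04) and Ctnnd2 (-3.01) followed. The highest ratios were 2.17 in Gabrg3, a GABA receptor gene on chromosome 7 (22 to 99 reads), 1.78 in Zc3h12b on the X chromosome, 1.75 in Ksr2, 1.64 at the olfactory receptor gene Olfr504 and 1.59 (1.17 to 2.03) at Sox3, a transcription factor gene on the X chromosome (60890001 to 60896000, 62 to 187 reads). Most of these ratios followed how much of the region was called: the Celf5 region had 26.4 kb of control island and 2.2 kb of DMA island, and the Gabrg3 region 0.4 and 4.8 kb. Per kb of called island the ratios of Gabrg3, Ksr2, Olfr504, Rbfox3 and Ctnnd2 turned the other way. Those of Celf5, Dmrt3, Tlx1 and Zc3h12b came to -0.24, -0.16, -0.34 and 0.10, and that of Sox3 to 1.01. Over the gene and 2 kb around it, the covered length of Ksr2 and Ctnnd2 went against the ratio of their region. Ksr2 had 72.2 kb in the control and 53.2 kb in the DMA library, and Ctnnd2 45.4 and 52 kb.

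The X chromosome stood apart from the autosomes. It carried 591 islands in the control library and 1174 in the DMA library, a ratio of 1.99, whereas the ratio of the autosomes lay between 0.928 (chromosome 11) and 1.10 (chromosome 1). On X, 76 islands were found in the control library only and 653 in the DMA library only. Its covered length was 1.98 Mb in the control and 3.32 Mb in the DMA library. Over regions covered by at least 80% in both libraries, the median log2 ratio was -0.02 on X (-0.063 to 0.0078, 208 regions), -0.28 on the autosomes and -0.41 on Y (-0.53 to -0.33, 29 regions). The Y chromosome carried 86 control and 63 DMA islands.

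**Figure D3:**
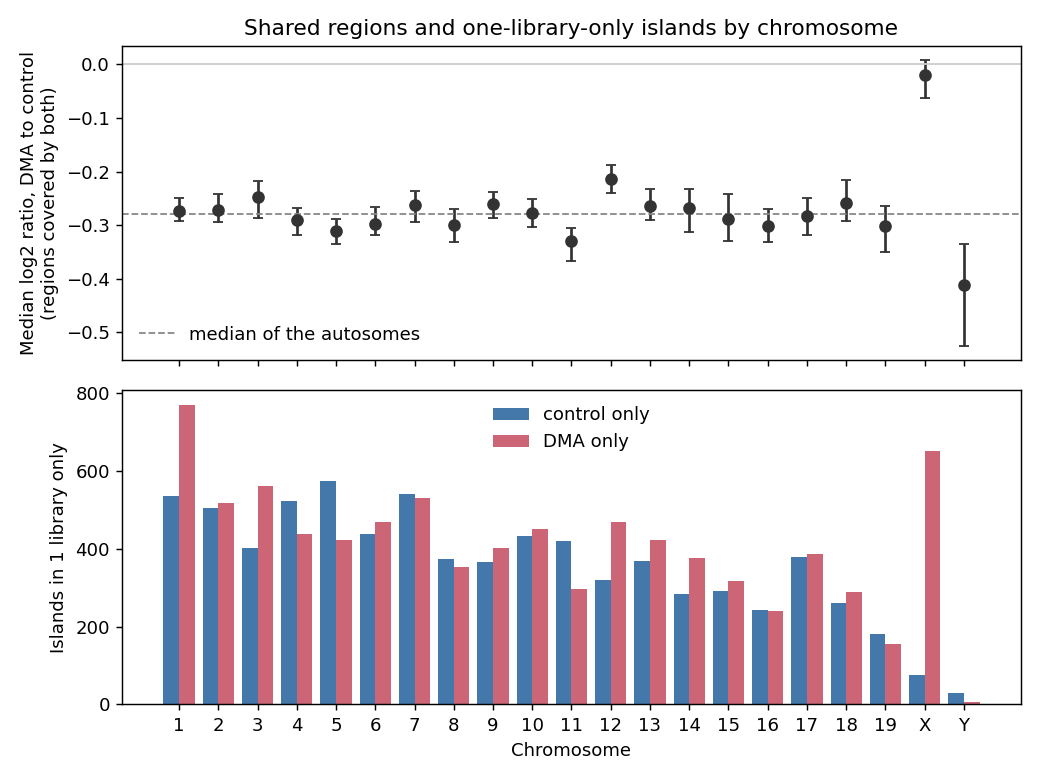
Top, median log2 ratio of DMA to control reads per chromosome over regions of which the islands of each library cover at least 80%, with the median of the autosomes as a dashed line. The 95% intervals of the median reflect the spread between regions and not between mice. Bottom, number of islands found in 1 library only. X lies at -0.02 and Y at -0.41, around the autosomal median of -0.28, and X has 653 islands in the DMA library only against 76 in the control library only.

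Fewer genes carried an island in the DMA library. Of 21887 protein-coding genes, 7625 (34.8%) had an island within the gene or 2 kb of it in the control library and 6712 (30.7%) in the DMA library. Both libraries marked 6021 genes, the control library alone 1604 and the DMA library alone 691. Protein-coding gene bodies made up 38.2% of the bases of control islands without a counterpart and 25.5% of those of DMA islands without a counterpart, beside 34.5% and 33.3% in shared islands and 38.7% of the mapped span of the chromosomes.

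Of 401 genes chosen by symbol as KRAB-type zinc finger genes, many of which encode repressors of retrotransposons, 270 were overlapped in the control library and 258 in the DMA library. The 25 control-only members included Zfp110, Zfp853 (11.4 kb), Zfp646 (8.8 kb) and Zfp113 (6.8 kb), and the 13 DMA-only members included Zfp329, Zfp660 (6.0 kb), Zfp960 and Zfp385c. The net difference of -12 genes lay at the 91.6 percentile of 10000 random lists matched on gene length, whose median was -21. The mean difference in covered share, -3.58 percentage points, lay at the 4.82 percentile, but these lists were not matched on cover. The zinc finger genes marked in the control library had a total covered length in the DMA library of 86.9% of that in the control library, above each of 10000 random lists matched on covered bases and read density (median 77.7%). Clustered protocadherins were covered in 56 and 55 of 57 genes, with Pcdhb1 the single difference (percentile 55.2). Their total covered length in the DMA library was 102.5% of that in the control library, also above each of the cover-matched lists (median 82.5%). Neighbouring protocadherin or zinc finger genes can share an island, such as Zfp646 and Zfp668, so the same bases were counted more than once. The members are therefore not independent of each other, while the random lists were drawn gene by gene. For the protocadherins the mean covered share was 53.1% in the control and 50.3% in the DMA library. Their mean difference of -2.85 points lay at the 44.0 percentile of lists matched on length alone. The median difference of -0.64 points lay at the 0.11 percentile of those lists. Olfactory receptors were covered in 73 and 68 of 1110 genes (percentile 99.7, and 68.6 of cover-matched lists for the ratio of covered lengths), with Olfr1459 and Olfr741 among 30 control-only and Olfr108 and Olfr161 among 25 DMA-only members. Vomeronasal receptors were covered in 68 and 67 of 355 (percentile 96.2, and 99.6 of cover-matched lists), with Vmn2r12 in the control library only and Vmn2r26 in the DMA library only. Germline genes silenced in somatic cells were covered in 29 and 27 of 45 (percentile 47.7), with Dpep3 and Asz1 in the control library only. Secreted and detoxification families were covered in 81 and 69 of 250 (percentile 51.0), with Cyp2b9 (11.9 kb) and Serpina9 (11 kb) among 18 control-only and Cyp2c38 among 6 DMA-only members. With only the upper 50% of islands by reads, Zfp960, Pcdhb1, Dpep3, Asz1, Cyp2c38 and the olfactory and vomeronasal receptor genes named here no longer differed, and the difference at Cyp2b9 was -2.66 kb.

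The Hox genes, which set position along the body axis, were less covered in the DMA library. Of 39 genes 32 were overlapped in the control and 27 in the DMA library. Hoxc6 (10.9 kb), Hoxc9 (10.6 kb), Hoxc5 (6.19 kb) and Hoxd8 (5.0 kb) were among the 5 marked in the control library only, and none was marked in the DMA library only. Hoxd8 no longer differed with the upper 50% of islands by reads. The mean covered share of a Hox gene was 57.2% in the control and 36.2% in the DMA library. Both the median difference, -9.31 percentage points, and the mean difference, -21.1 points, lay below each of the 10000 random lists. These lists were matched on length alone and drawn gene by gene. Hox genes lie in clusters where neighbours can share an island, such as Hoxc5 and Hoxc4, so they are not independent of each other. The net count of -5 lay at the 7.36 percentile. The total covered length of the 32 Hox genes marked in the control library was 59.4% of the control value in the DMA library, against a median of 65.1% (95% range 49.6 to 81.7%) for random genes with similar covered bases and read density in the control library. Imprinted genes, expressed from the copy of 1 parent, were overlapped in 44 of 53 cases in either library (percentile 76.8), but their mean covered share was 36.8% in the control and 29.0% in the DMA library, with a mean difference at the 0.26 percentile of lists matched on length alone. The total covered length of the protein-coding ones was 79.3% of the control value in the DMA library, at the 40.4 percentile of cover-matched lists (median 80.5%). Peg12 and Ndn were marked in the control library only, and Ube3a and Dcn in the DMA library only, but Ndn, Ube3a and Dcn no longer differed with the upper 50% of islands by reads.

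Genes of the cell cycle and of lung tumours differed by 9 control-only and 0 DMA-only members among 51, with 22 overlapped in the control and 13 in the DMA library. This net count lay at the 0.29 percentile of the random lists, the lowest of the 14 lists, while the mean difference in covered share lay at the 24.2 percentile. The total covered length of the members marked in the control library was 82.8% of the control value in the DMA library, at the 93.0 percentile of cover-matched lists. This total gives more weight to members with long cover. The mean covered share of a gene of this list was 6.12% in the control and 2.28% in the DMA library. The control-only members included Ccnd3, a D-type cyclin (13 kb), the receptor kinase gene Ret (11.4 kb), the cell cycle inhibitor gene Cdkn1a (8.4 kb, 201 reads) and Keap1, the brake on the NRF2 stress response (4.53 kb). No island overlapped the cyclin gene Ccnd1 in either library. The keratin gene Krt8 lay at an island on chromosome 15 (101990401 to 101999600) with 296 control and 109 DMA reads, a log2 ratio of -1.44 (-1.77 to -1.12) and of -1.06 relative to the median. The called length was 9.2 kb in the control and 5.4 kb in the DMA library, and per kb of called island the log2 ratio was -0.67. Both islands covered the same 4.89 kb in and next to the gene. Of 53 keratin genes 7 were overlapped in each library (percentile 92.7), and the mean covered share was 3.83% in the control and 2.85% in the DMA library.

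Of 32 lung epithelial markers 13 were overlapped in the control and 8 in the DMA library, with 5 control-only and 0 DMA-only members (percentile 4.33). The mean difference in covered share lay at the 18.5 percentile and the ratio of covered lengths, 56.7%, at the 19.7 percentile of cover-matched lists, and with at least 1 kb of island in the gene the counts were 5 and 1. Examples were the aquaporin gene Aqp5 of alveolar type I cells (7.8 kb), Nkx2-1, the transcription factor of lung identity (5.4 kb), the cadherin gene Cdh1 (2.8 kb) and Cyp2f2 of club cells (2.2 kb). Of 39 endothelial, mesenchymal, blood and other markers 17 and 11 were overlapped, with 6 control-only and 0 DMA-only members (net count at percentile 2.59, mean difference at 7.13, ratio of covered lengths at 8.91), among them Pdgfra (7.68 kb), Sox10 (6.0 kb), Tbx4 (4.6 kb) and Tubb3 (1.4 kb). Cdh1, Cyp2f2 and Tubb3 no longer differed with the upper 50% of islands by reads.

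Genes of arsenic handling and of the mark itself differed by few members. Of 46 genes of arsenic metabolism and the oxidative stress response 11 were overlapped in the control and 9 in the DMA library (percentile 53.0). Keap1, Nfe2l2, which encodes NRF2, and Gstp2 were marked in the control library only, and the efflux pump gene Abcc1 in the DMA library only. The arsenic methyltransferase gene As3mt carried 104 control and 66 DMA reads, a log2 ratio of -0.66 (-1.12 to -0.20) and of -0.27 relative to the median. The interval includes the median of -0.38. The called length was 3.6 kb in the control and 2.6 kb in the DMA library, and per kb of called island the log2 ratio was -0.19. Of 39 genes of H3K9 methylation and heterochromatin 21 and 19 were overlapped (percentile 35.9). Kdm4a and Kdm7a, which encode histone demethylases, the DNA methyltransferase gene Dnmt1 and Daxx were marked in the control library only, and Phf8, on the X chromosome, and Prdm2 in the DMA library only. The islands at Kdm7a and Daxx lay outside the gene body, and Dnmt1, Phf8 and Abcc1 no longer differed with the upper 50% of islands by reads. The H3K9 methyltransferase genes Suv39h1 and Setdb1 had no island in either library.

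**Figure D4:**
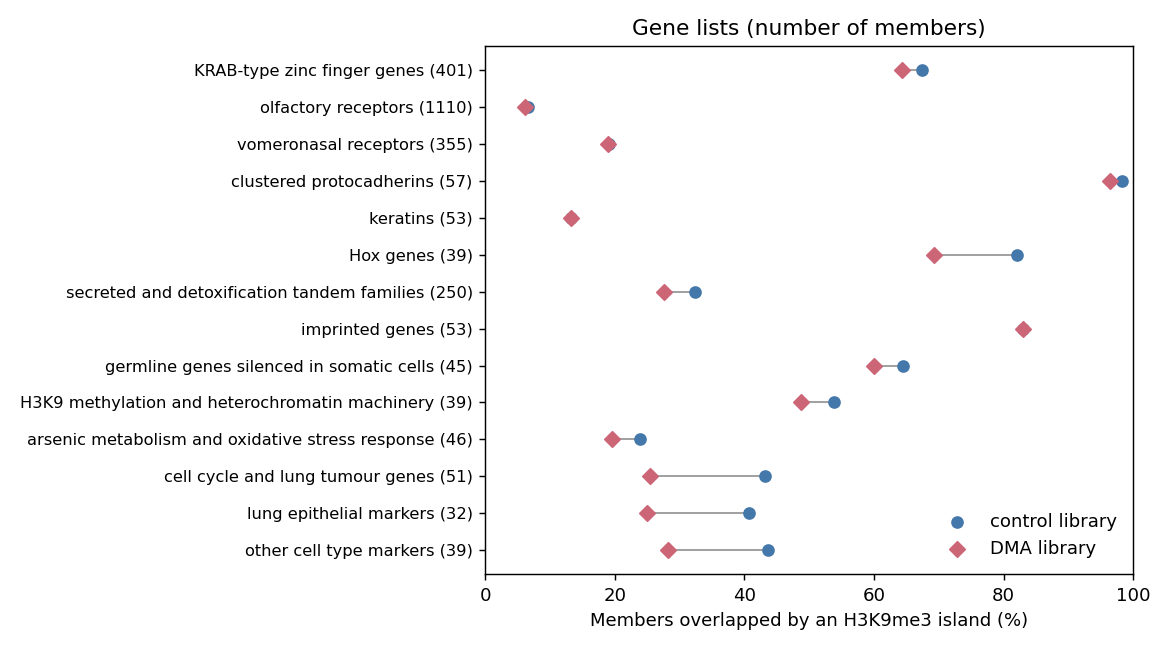
Share of the members of each of the 14 gene lists, fixed before the data were examined, that an H3K9me3 island overlapped in the control library (circles) and in the DMA library (diamonds), with the number of members in parentheses. The share was 43.1% in the control and 25.5% in the DMA library for cell cycle and lung tumour genes, and 83.0% in both for imprinted genes.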

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

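The regions covered by at least 80% in both libraries, the X chromosome under other island sets, the gene context on autosomes and the cover-matched lists were alternatives chosen after the data were seen. Across all alternatives run, the control library kept the longer covered length and more genes marked in 1 library only. None of these alternatives made the reads in islands equal between the libraries. They therefore cannot separate this direction from the difference in read totals. The X ratio of islands lay between 1.67 and 2.40. Keeping the upper 50% by reads left 17618 control and 18493 DMA islands, of which 3343 and 3765 had no counterpart, since fewer islands were compared, and 81.0% and 79.6% were shared. The order of the shared percentages of control and DMA islands changed with the setting: 74.5% and 79.8% with islands of at least 2 kb, 77.4% and 79.3% with equal numbers of islands, 70.3% and 74.5% with at least 50% of the island covered, and 79.2% and 77.6% within 1 kb. On autosomes 78.1% of DMA islands were shared. The DMA library had more islands, and more without a counterpart, as deposited, but fewer of both with islands of at least 2 kb, and fewer without a counterpart with equal numbers and with 50% covered. The cause was not tested.

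The median log2 ratio was 0.087 after scaling to total reads in islands, 0 by construction after scaling to the median, -0.39 for regions of at least 100 reads, -0.16 per kb of called island and -0.28 for regions covered by at least 80%. Per kb of called island the ratios turned to -1.42 for Gabrg3, -0.46 for Ksr2, -0.027 for Olfr504, 0.42 for Rbfox3 and 1.03 for Ctnnd2, because the called lengths differed. With at least 1 kb of island in the gene the net count of DMA-only minus control-only members was 1 for vomeronasal receptors, -1 for keratins and 0 for germline genes. With equal numbers of islands it was -12 for olfactory receptors, -2 for vomeronasal receptors and -1 for imprinted genes. The cause was not tested. Of the 368 gene values that 92 named genes gave under alternatives, 307 kept the direction of the covered length, 45 had no difference left and 0 reversed. The remaining 16 belong to genes with no difference in covered length as reported. These alternatives only removed islands or narrowed the window, so a gene marked in 1 library only could lose its difference but not reverse. For such genes the absence of reversals was fixed in advance. Against cover-matched lists the ratio of covered lengths lay at percentiles 68.6 for olfactory receptors, 58.7 for keratins, 32.5 for secreted and detoxification families, 97.6 for germline genes, 20.8 for heterochromatin genes and 55.5 for arsenic and stress genes.

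Promoter windows, exons, introns and the gene start alone were not run, since strand and transcript starts were not used here. No paired analysis was possible because each group has 1 library and no test was made. Weak islands limit these comparisons, since 42.5% of control and 51.9% of DMA islands with under 50 reads had no counterpart.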

Other observations

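All patterns below were noticed in these data. The tests of the Y chromosome and of gene density across chromosomes, the list of developmental genes, and the comparisons of control-covered bases also covered in the DMA library and of developmental genes matched on covered bases were chosen after the patterns were seen.

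Each Hox cluster was covered less in the DMA library. HoxC had 63.8 kb of island in the control and 17.8 kb in the DMA library, with 1457 and 313 reads. HoxD had 60.2 and 33.2 kb, HoxB 74.4 and 43.4 kb, and HoxA 54.9 and 36.9 kb. Among 191 other genes of developmental transcription factor families, 126 were overlapped in the control and 92 in the DMA library, with 39 control-only and 5 DMA-only members, and the mean covered share was 35.3% and 19.8%. Among the largest losses, named after their values were seen, Lhx9 (13 kb), Barhl1 (12 kb), Nkx2-2 (11 kb) and Pax9 (8.51 kb) were marked in the control library only. Sox5 was marked in both, over 91.8 and 75 kb.

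Some strong islands had no counterpart. They included control islands of 1234 reads on chromosome 18 (74364401 to 74376400), outside annotated genes, and of 856 reads on chromosome 3 (95412801 to 95428000), and a DMA island of 639 reads at Zfp992 on chromosome 4 (146454001 to 146461000).

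Over X regions covered by both libraries, a preference for weak regions does not account for all of the higher log2 ratio. It lay 0.145 (0.096 to 0.21, 208 regions) above autosomal regions of the same control density and length. Without that matching the difference was 0.26, so part of it went with region strength. The 653 X islands found in the DMA library only are not among these regions, so whether a preference for weak regions accounts for them was not tested. Low gene density does not account for the X ratio of DMA-only to control-only islands. The trend over 19 autosomes predicted up to 1.75 and X had 8.592. A candidate explanation is some female DNA in the DMA pool, since Y regions outside the end of the chromosome lay -0.148 (-0.29 to -0.076, 25 regions) from the autosomal median, and after matching X was 10.6% higher (6.86 to 15.9%) and Y at -8.20% (-13.1 to -5.78%), while autosomes lay within -0.051 to 0.053 on the log2 scale. Read as a share of female DNA, the X and Y values overlap within their intervals with matching and, at their edges, without it, where X gave 19.7% (16.2 to 21.4%) and Y 9.75% (5.11 to 18.4%), so its size depends on the matching. The labels give all mice as male, reads on Y are hard to place because of its repeats, whether so small a dose doubles the islands was not tested, and an effect of DMA on X stays open.

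Control islands without a counterpart lay in genes more than DMA ones. Control islands with at least 50% of their length in protein-coding gene bodies lacked a counterpart in 23.4% of cases. The value for all other islands of similar reads and length was 16.6%. The difference was 6.775 percentage points (5.39 to 8.29 on resampling the autosomes) and was positive in each of the 19 autosomes. In the other direction, for DMA islands, it was 0.656 points (-0.376 to 1.70). The reads and length of an island alone thus do not account for the pattern. Local background was not matched, as the input library was not analysed here, so fewer reads in the DMA islands are not excluded as a cause. A regional bias between the libraries may contribute. It was examined over 3446 regions covered by at least 80% in both libraries and away from any annotated gene. There the log2 ratio fell with the number of coding genes nearby (Spearman rho -0.146, negative on 18 of 19 autosomes, where regions are not independent replicates). Base composition was not tested, as no genome sequence was used here, and a biological effect of DMA on genes stays open.

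The loss of covered length at Hox genes extended to regions of developmental transcription factor genes in general, whose mean difference of -15.5 percentage points lay at percentile 0 of length-matched random lists, against -3.56 in those lists. The total covered length of Hox genes marked in the control library was 59.4% of the control value in the DMA library. This lay at percentile 23.54 of random genes matched on covered bases and density (median 65.1%). Of their control-covered bases 56.8% were also covered in the DMA library, at percentile 74.6. Fewer reads in the DMA islands may thus account for the Hox genes. The matched genes would share a library-wide effect of DMA as well, so the comparison cannot tell these causes apart. Over whole clusters the ratio was 27.9% for HoxC and 55.1 to 67.2% for the others. Single clusters were not compared with random genes. For the other developmental genes a role of fewer reads stays open, as the result depended on the matching. Their ratio of 60.3% lay at percentile 24.23 of genes matched on covered share and density but at percentile 2.48 of genes matched on covered bases. The part of their control-covered bases also covered in the DMA library, 54.8%, lay at percentiles 31.2 and 31.1 under these matchings. Hox genes lie in 4 clusters and are not independent of each other, and an effect of DMA on such islands as a class stays open.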
